A study of Mus musculus with 14 samples.

How the data were processed

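Total RNA from thymic lymphomas of 14 mice was measured on 1 Affymetrix expression array per tumour. All mice carried the p53 R270H mutation on both alleles on a mixed C57BL/6-129/SvEvTac background and differed in their Hif1a genotype, with 5 Hif1a+/+, 5 Hif1a+/- and 4 Hif1aKI/+ tumours. The labels do not say what the knock-in (KI) allele carries. Per the labels, 100 ng of RNA was amplified by in vitro transcription, converted to cDNA and labelled with biotin, and the labels name no batch, sex or age.

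The deposited values are log2 probe set summaries made by the authors, whose notes name GCRMA and Partek without versions. GCRMA corrects each probe for background by its sequence, normalizes the arrays and summarises the probes of a probe set. The genome build is not given in the sources used here, and raw intensities were not analysed here. The table has 18264 probe sets, of which 16602 name 1 gene, 603 name several and 1059 name none. The values run from about 1.8 to about 15.6, and the array medians lie between 7.91 and 8.03. The distribution has a low mode of probe sets with no signal above background, bounded at 4.41, and 28.5% of the genes have a mean below that boundary. A difference from a group mean below it is measured against background, so its size is uncertain. The number of arrays limits the precision of every difference given.

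Probe sets naming exactly 1 gene were kept, and the probe set with the highest mean over the 14 arrays stood for a gene, which left 10254 genes, 3999 of them with more than 1 probe set. No filter on level was applied. One linear model with a mean per genotype was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with default moderation), and the 3 pairwise differences and the moderated F test were read from that fit. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over all genes, and the threshold was an adjusted p of 0.05. Errors given with a log2 difference are standard errors of the fit (SE), and errors given with a group mean are standard deviations between tumours (SD).

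Gene lists for pathways, T cell stages, other cell types and RNA quality were written before the data were examined, as were the comparisons, tests, named genes and most alternatives. Of 38 lists, the 37 other than the sex-linked genes were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 measured members. Each list was also tested by camera with the correlation estimated from the data and by fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. A count of genes adjusted over the list alone was made for each list.

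The named genes are a fixed set of HIF, Notch and hypoxia genes, up to 10 genes per direction in each comparison (those past the threshold, then those of smallest unadjusted p with a log2 difference of at least 1, named as not past it), and the 4 members of smallest unadjusted p in each list discussed. Genes outside that rule are named as chosen after their values were seen. Hif1a and Epas1 levels were compared by two-sided exact permutation tests over all 252 or 126 assignments of the arrays. The 25 nearest measured genes on each side of Hif1a were compared with all other genes by Fisher's exact test, since a targeted allele can carry flanking sequence of the donor strain. The fold changes of the genotypes against the shared Hif1a+/+ tumours were correlated beside 100 simulations of unchanged groups and beside 20 splits of the controls.

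The procedure was tested on simulated data with the same group sizes and 200 changed genes in each of 5 runs. For Hif1a+/- against Hif1a+/+ it recovered 48% of the genes changed by 1 on the log2 scale and 74% of those changed by 2, with 6.4 false calls per run. The shares were 36.4% and 73% for Hif1aKI/+ against Hif1a+/+ and 38.8% and 71.2% for Hif1a+/- against Hif1aKI/+. The changed genes were drawn at random from all genes, those below the low-mode boundary included, and each kept its own observed spread. That spread can be small at background, so the shares do not give the recovery among expressed genes alone. The glycolysis list, shifted by 0.5, was found in 5 of 5 runs in each comparison. The simulated genes varied independently, whereas the estimated correlation was 0.409 in the Myc and ribosome biogenesis list. The runs therefore do not show how the list test behaves on correlated genes.

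Alternatives covered a filter on level, quantile normalization, centring on array medians, trend and robust moderation, array weights, fits of only the compared groups, the mean of a gene's probe sets, all probe sets tested singly, a Y-linked covariate, other thresholds, other list tests and leaving out each array. The replicate numbers of the labels were tried as a block although same-numbered arrays of different genotypes did not resemble each other (mean correlation of residual values -0.0003 over 13 pairs). Fits without 3 Hif1a+/+ arrays, with a thymic epithelial covariate and with a cell cycle covariate were added after the values were seen. The sex-linked list had fewer than 5 measured members and was not tested, and the mean of its Y-linked genes served as a covariate. Trp53 was not among the probe sets that name 1 gene and was not analysed here. The 1662 probe sets that name several genes or none were left out of the named comparisons. In a fit of all probe sets, with p adjusted over all of them, 0 of these 1662 passed in any comparison by limma, as did 0 of the others. At an unadjusted p under 0.05 there were 118, 44 and 32 of the 1662. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.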

Results

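Gene expression was measured in thymic lymphomas of p53 R270H/R270H mice, taken when the animals showed respiratory distress, to find differences between Hif1a genotypes that could account for changes in tumour onset and incidence. The groups held 5 Hif1a+/+ tumours, 5 Hif1a+/- tumours and 4 Hif1aKI/+ tumours with 1 knock-in allele. Each tumour was hybridised to 1 array and 10254 genes were tested on log2 values. Correlations between arrays ran from 0.941 to 0.974, with a median of 0.960 within groups and 0.959 between groups.

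Hif1a, which encodes the oxygen-regulated subunit of HIF-1, gave a lower signal in the tumours with the knock-in allele and a similar signal in Hif1a+/- and Hif1a+/+ tumours. At the probe set of highest mean, the level was 12.02 ± 0.22 (SD, n = 4) in Hif1aKI/+, 12.55 ± 0.22 (SD, n = 5) in Hif1a+/- and 12.68 ± 0.26 (SD, n = 5) in Hif1a+/+ tumours. Hif1aKI/+ lay 0.66 below Hif1a+/+ on the log2 scale, 1.58-fold lower, with all 4 tumours below the lowest Hif1a+/+ tumour (exact permutation p = 0.00794, the smallest these groups can give). A second probe set was 3.57-fold lower in Hif1aKI/+ than in Hif1a+/+ (exact permutation p = 0.00794), while the third differed by -0.76 without passing (exact permutation p = 0.119). In the fit over all genes the difference at the first probe set did not pass (limma adjusted p = 0.984), and adjusted over the list alone Hif1a was the 1 gene of the HIF pathway components that did (adjusted p = 0.0133).

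Between Hif1a+/- and Hif1a+/+ tumours the Hif1a signal differed by -0.13 (exact permutation p = 0.452), less than the spread between tumours. The position of these probe sets relative to the altered exons is not known here, so the signal does not measure the dose of intact transcript. Epas1, which encodes HIF-2alpha, lay below the low-mode boundary of 4.41 in all 14 tumours, and its difference between Hif1aKI/+ and Hif1a+/+ was 0.22 (exact permutation p = 0.0873). It reached 2.82 in Hif1aKI/+ tumour 5, and without that tumour the difference was 0.03.

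**Figure D1:**
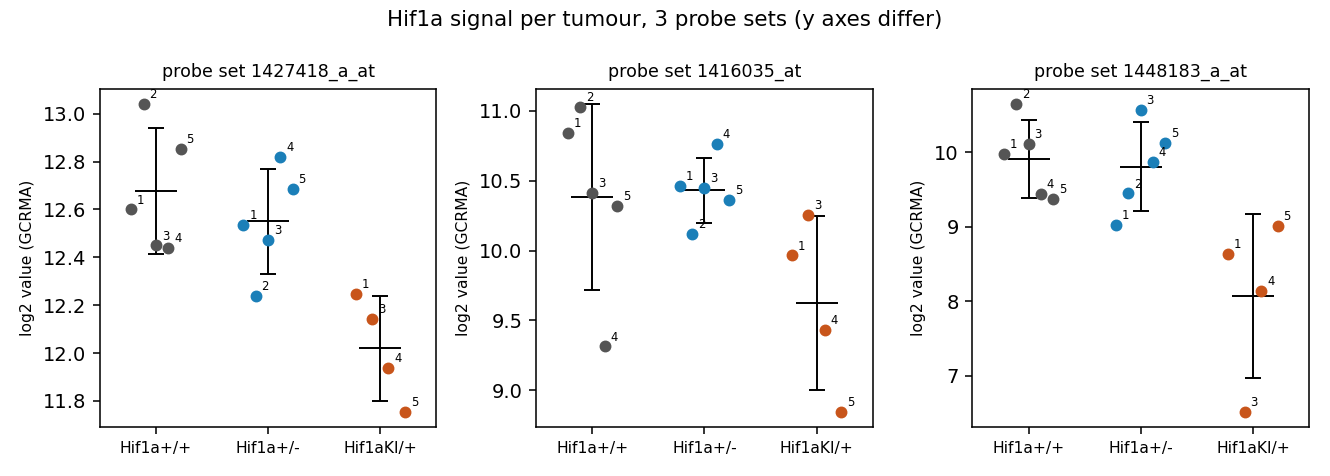
Log2 signal (GCRMA) of 3 Hif1a probe sets in each tumour by genotype, with numbers giving the replicate and bars the mean and SD. In the left panel the 4 Hif1aKI/+ tumours lie between 11.75 and 12.25, all below the lowest Hif1a+/+ tumour at 12.44.

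The comparison of Hif1a+/- with Hif1a+/+ tumours asks what a single functional Hif1a allele changes in these lymphomas. Stab1, the scavenger receptor stabilin-1 of macrophages and sinusoidal endothelium, fell 2.42-fold, from 9.01 ± 0.33 (SD, n = 5) to 7.73 ± 0.23 (SD, n = 5). Dhx15, an RNA helicase of the splicing machinery, fell 1.23-fold, from 13.6 ± 0.07 (SD, n = 5) to 13.3 ± 0.04 (SD, n = 5). Genes of the Notch pathway, of ribosome biogenesis, of the cell cycle and of the extracellular matrix fell as groups by camera, and interferon-induced, MHC class II and thymic epithelial genes rose, none of them with an estimated correlation (adjusted p = 0.31 to 0.54). The ribosome biogenesis and cell cycle lists did not pass without Hif1a+/- tumour 5. Stab1 (log2 difference -1.28, SE 0.17) and Dhx15 (-0.30, SE 0.04) each had an adjusted p of 0.0499, and every Hif1a+/- tumour lay below every Hif1a+/+ tumour. At an unadjusted p under 0.05 there were 441 higher and 373 lower genes, where chance gives 512.7 in all. Next in rank stood Hspb11 at 0.87 (adjusted p = 0.0569), named after its value was seen.

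Among the genes next in rank that did not pass, the lower ones included Svep1 (-1.63) and Frmd4b (-2.04), each with an adjusted p of 0.207, the Svep1 means of both groups lying below the low-mode boundary. Others were the extracellular proteoglycan gene Ogn (-3.06), the lymphocyte receptor gene Cd160 (-2.95), the carnitine transporter gene Slc22a21 (-2.40), Rassf8 (-1.89), the zinc finger gene Glis2 (-1.68) and Stard8 (-1.40). The higher ones were P3h4 (4.47), the laminin chain gene Lamb3 (2.68), Cdk20 (2.08), Gramd3 (2.08), Zfp707 (1.84), Tmco6 (1.77), Hint2 (1.49), Lpxn (1.31), the kinase gene Mapk7 (1.09) and the adhesion molecule gene Icam2 (1.07). All of these but Svep1 and Frmd4b had an adjusted p of 0.408. Lamb3 and Zfp707 had a Hif1a+/+ mean below the low-mode boundary, and Slc22a21 and Stard8 a Hif1a+/- mean below it.

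Of 26 measured genes of the Notch pathway and its targets, 23 were lower in Hif1a+/- tumours, 8 of them at an unadjusted p under 0.05, and none passed singly over all genes or adjusted over the list alone. Of the 26 genes 9 had a mean below the low-mode boundary. The list fell in camera (adjusted p = 0.00075), but not with an estimated correlation (adjusted p = 0.31, unadjusted p = 0.0088), and in fry its adjusted p was 0.043. The target genes Dtx1 (-4.51, SE 1.8), Hes1 (-2.77, SE 0.98) and Ptcra (-1.98, SE 0.70), the receptor gene Notch3 (-2.03, SE 0.70) and the IL-2 receptor gene Il2ra (-4.37, SE 1.47) had the larger differences. The Hif1a+/- means of Il2ra (3.36) and Hes1 (4.24) lay below the low-mode boundary. Igf1r, at -1.45, had both group means below the boundary. Notch1 differed by -0.81, Nrarp by -1.28, Adam10 by -0.36 and Myc by -0.35, while Ccnd3 was higher at 0.71. Within the genotype the tumours were uneven, with Dtx1 at 1.90 in Hif1a+/- tumour 5 and 2.62 in tumour 2 but at 11.13 and 11.27 in tumours 3 and 4. Double-negative thymocyte markers, which share 6 genes with the Notch list, fell too, with 10 of 16 lower (camera adjusted p = 0.026, 0.042 in fry and adjusted p = 0.31 with an estimated correlation). Their mean moderated statistic against other genes was -0.93, and they did not pass in 3 fits without 1 tumour. It was -0.76 without Hif1a+/- tumour 5 (camera adjusted p = 0.091), -0.78 without Hif1a+/+ tumour 1 (0.0625) and -0.77 without Hif1a+/+ tumour 2 (0.075).

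**Figure D2:**
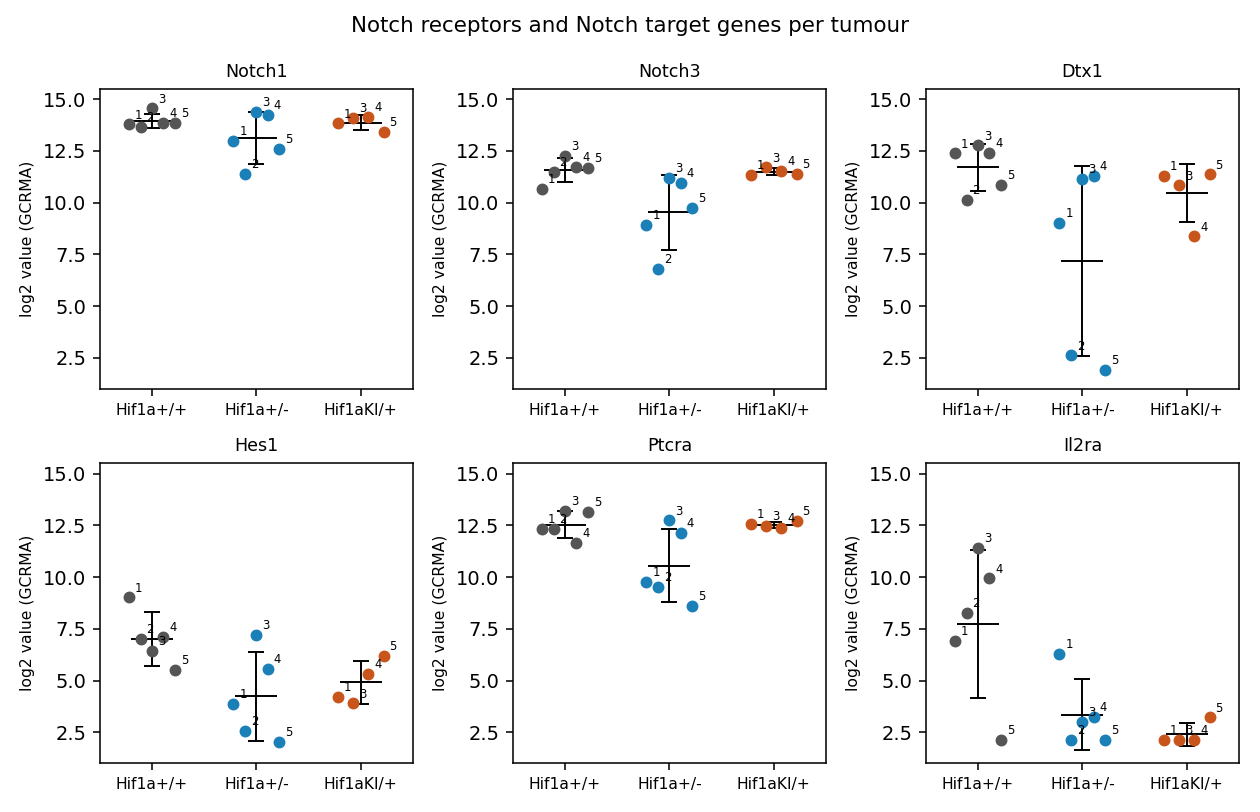
Log2 signal (GCRMA) of Notch receptors and Notch target genes in each tumour by genotype, with numbers giving the replicate and bars the mean and SD. Notch3 lies between 6.78 and 11.20 in Hif1a+/- tumours and between 11.32 and 11.69 in Hif1aKI/+ tumours.

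Genes of growth and proliferation fell by camera in Hif1a+/- tumours, but not in the fit without Hif1a+/- tumour 5. Of the Myc and ribosome biogenesis genes 25 of 27 were lower, among them the RNA polymerase I subunit gene Polr1b (-1.20), Nolc1 (-0.69), Ddx21 (-0.24) and Eif5a (-0.17), with a camera adjusted p of 3.4e-05 (adjusted p = 0.52 with an estimated correlation). Of the cell cycle genes 32 of 39 were lower, with Mcm4 at -0.76, Mcm2 at -0.52, Kif23 at -0.42 and Rrm2 at -0.32 (camera adjusted p = 0.00082, adjusted p = 0.54 with an estimated correlation). Of the DNA repair genes 18 of 22 were lower, with Blm at -0.71, Prkdc at -0.70, Brca2 at -0.58 and Lig1 at -0.40 (camera adjusted p = 0.029, adjusted p = 0.52 with an estimated correlation). Glycolysis genes had 14 of 18 lower, with Slc2a3 at -0.72, Aldoa at -0.50, Pkm at -0.36 and Pgam1 at -0.30 (camera adjusted p = 0.026, adjusted p = 0.52 with an estimated correlation). Without Hif1a+/- tumour 5 none of these 4 lists passed. The mean moderated statistic against other genes went from -0.89 to -0.21 for the cell cycle (camera adjusted p = 0.56) and from -0.72 to -0.30 for DNA repair (0.52). It went from -1.25 to -0.60 for Myc and ribosome biogenesis (camera adjusted p = 0.085) and from -0.83 to -0.52 for glycolysis (0.25). DNA repair did not pass without Hif1a+/+ tumours 1 (-0.63, camera adjusted p = 0.062), 3 (-0.51, 0.16) or 4 (-0.48, 0.15) either. Glycolysis did not pass without Hif1a+/- tumour 4 (-0.71, camera adjusted p = 0.076) or Hif1a+/+ tumours 1 (-0.56, 0.14), 2 (-0.61, 0.098) or 3 (-0.71, 0.051). With the mean of the cell cycle list as a covariate, the statistic was -0.45 for Myc and ribosome biogenesis (camera adjusted p = 0.22). It was -0.18 for DNA repair (camera adjusted p = 0.62) and -0.49 for glycolysis (0.27). The 26 hypoxia-induced and HIF target genes did not shift (camera adjusted p = 0.62, 17 lower), with Lox at -1.83, Hmox1 at -1.01, Jmjd6 at 0.62, Mxi1 at 0.45, Vegfa at 0.42, Slc2a1 at -0.11 and Bnip3 at -0.04. Pgk1 differed by -0.13 and Ldha by -0.16.

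Markers of other cells in the tumours moved in both directions. Fibroblast and matrix genes fell, 17 of 21 lower, and 4 passed adjusted over the list alone against 0 over all genes: Col5a1 (-2.14), Col3a1 (-1.44), Fn1 (-1.85) and Pdgfra (-2.16), with a camera adjusted p of 3.4e-05 for the list (adjusted p = 0.52 with an estimated correlation). Macrophage markers had 18 of 22 lower, with Cd163 at -2.99, Cd14 at -2.17, Mrc1 at -1.55 and Csf1r at -0.53 (camera adjusted p = 0.0030, adjusted p = 0.52 with an estimated correlation). The macrophage list did not pass without Hif1a+/+ tumour 2 (statistic from -1.01 to -0.59, camera adjusted p = 0.090) or without Hif1a+/- tumour 5 (-0.67, 0.085). Nor did it pass with array weights (-0.48, camera adjusted p = 0.27) or with the filter on level (-0.74, 0.069). Endothelial markers, 10 of 17 with a mean below the low-mode boundary, had 13 of 17 lower, with Plvap at -0.96 and Pecam1 at 0.81, and Eng and Cdh5 below the boundary in both group means (camera adjusted p = 0.026, adjusted p = 0.56 with an estimated correlation). That list did not pass without Hif1a+/+ tumour 5 (statistic from -0.83 to -0.42, camera adjusted p = 0.38) or without Hif1a+/- tumours 1 (-0.70, 0.069), 2 (-0.59, 0.091) or 4 (-0.71, 0.079). All 8 adipocyte genes were lower, among them Car3 (-3.90), Retn (-2.79), Adipoq (-1.72, both group means below the boundary) and Pparg (-1.16), with a camera adjusted p of 0.0043 (adjusted p = 0.52 with an estimated correlation). The mean of the adipocyte list was uneven among Hif1a+/+ tumours, at 7.916, 9.044 and 8.114 in tumours 2, 3 and 5. In Hif1a+/+ tumours 1 and 4 it was 6.079 and 5.096, not above the Hif1a+/- range of 5.328 to 6.362.

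Interferon-induced genes rose, with 26 of 27 higher, among them Mx1 (2.45), Irf7 (2.02), Irf9 (1.30) and Igtp (0.81), and a camera adjusted p of 3.4e-05 (adjusted p = 0.52 with an estimated correlation, unadjusted p = 0.045). Dendritic cell and MHC class II genes had 11 of 13 higher, with H2-Eb1 at 1.12, Cd74 at 0.94, Cst3 at 0.65 and H2-Ab1 at 0.48 (camera adjusted p = 0.0021, adjusted p = 0.52 with an estimated correlation). Thymic epithelial markers had 11 of 14 higher, with Krt18 at 3.66, Krt5 at 2.35, Krt14 at 1.89 and Ccl25 at 1.39 (camera adjusted p = 0.0043, adjusted p = 0.52 with an estimated correlation). Ribosomal protein genes had 17 of 25 higher by small amounts, and 2 of them passed adjusted over the list alone against 0 over all genes, Rpl19 (0.29) and Rps14 (0.25), beside Rpl11 (0.18) and Rpl22 (0.17), with a camera adjusted p of 0.026 (adjusted p = 0.56 with an estimated correlation). The statistic of the ribosomal list went from 0.76 to 0.32 with the arrays centred on their medians (camera adjusted p = 0.43). The list did not pass without Hif1a+/- tumours 1 (0.57, camera adjusted p = 0.12) or 4 (0.51, 0.20) or Hif1a+/+ tumour 3 (0.48, 0.20) either. The thymic epithelial list did not pass without Hif1a+/+ tumour 5 (statistic from 1.20 to 0.82, camera adjusted p = 0.057). With the mean of the thymic epithelial list as a covariate, the MHC class II statistic went from 1.275 to 0.39 (camera adjusted p = 0.40). Of the autophagy genes Gabarap (0.54) and Gabarapl2 (0.51) passed adjusted over the list alone and 0 over all genes, without a shift of the list (camera adjusted p = 0.25).

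In all, 14 of 37 lists passed, 4 higher and 10 lower, 0 of them with an estimated correlation and 2 in fry. Neither Stab1 nor Dhx15 passed with the arrays centred on their medians or in any of the 14 fits without 1 array (limma adjusted p = 0.0601 to 0.228 in the latter). Their differences stayed about as large, from -1.38 to -1.20 for Stab1 and from -0.31 to -0.27 for Dhx15 in those fits and at -1.32 and -0.34 with centring. Krt18 lay at 3.21, 3.56 and 3.45 in Hif1a+/+ tumours 3, 4 and 5, and 1 fit left these out for their low keratin signal, so it does not test the epithelial call. That fit called 45 genes and 8 lists. Lists lost in it were the MHC class II (statistic from 1.28 to -0.08, camera adjusted p = 0.89), interferon (0.12), cell cycle (0.11), DNA repair (0.54), endothelial (0.60) and ribosomal protein (0.51) ones. Without Hif1a+/- tumour 5, 8 lists passed.

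The comparison of Hif1aKI/+ with Hif1a+/+ tumours asks what the knock-in allele changes. Thymic epithelial genes, MHC class II genes and interferon-induced genes rose as groups by camera and adipocyte genes fell. None passed with an estimated correlation (adjusted p = 0.47 to 0.83). Against the same Hif1a+/+ tumours Stab1 was lower by -1.10 (SE 0.18), in all 4 tumours, and Psors1c2 was higher by 3.04 (SE 0.56), but limma called 0 genes (adjusted p = 0.715 and 0.793 for these), with 279 higher and 167 lower at an unadjusted p under 0.05 where chance gives 512.7. The Hif1a+/+ mean of Psors1c2 (2.31) lay below the low-mode boundary.

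All 14 thymic epithelial markers were higher in Hif1aKI/+ tumours, with the keratin genes Krt8 at 4.38, Krt18 at 4.10 and Krt5 at 2.48 and the chemokine gene Ccl25 at 1.26 (camera adjusted p = 1.3e-06, adjusted p = 0.47 with an estimated correlation, unadjusted p = 0.025). The difference came with a wide spread among Hif1a+/+ tumours, where Krt8 was 10.68 and 9.94 in tumours 1 and 2 but 3.10, 2.04 and 6.62 in tumours 3, 4 and 5. Of the MHC class II and dendritic cell genes 12 of 13 were higher, with Itgax at 1.90, Cd74 at 1.0, H2-DMa at 0.72 and H2-Ab1 at 0.57 (camera adjusted p = 0.00059, adjusted p = 0.83 with an estimated correlation). Interferon-induced genes had 24 of 27 higher, with Oasl2 at 2.22, Usp18 at 1.55, Igtp at 0.82 and Irgm1 at 0.60 (camera adjusted p = 0.00084, adjusted p = 0.83 with an estimated correlation). All 8 adipocyte genes were lower, with Retn at -2.23, Car3 at -2.21, Adipoq at -1.61 (both group means below the low-mode boundary) and Pparg at -1.0 (camera adjusted p = 0.045, adjusted p = 0.83 with an estimated correlation). The adipocyte list mean ran from 5.635 to 6.855 in Hif1aKI/+ tumours. Hif1a+/+ tumours 2, 3 and 5 lay above that range and tumours 1 and 4 (6.079 and 5.096) did not. With the mean of the epithelial list as a covariate, the mean moderated statistic against other genes went from 1.28 to 0.08 for MHC class II (camera adjusted p = 0.91) and from 0.90 to 0.56 for interferon (0.13). Of single tumours, MHC class II did not pass without Hif1aKI/+ tumour 1 (0.66, camera adjusted p = 0.080) and interferon not without Hif1aKI/+ tumour 4 (0.50, 0.094). The adipocyte statistic went from -1.08 to -0.64 with the Y-linked covariate (camera adjusted p = 0.24) and to -0.62 with the epithelial one (0.31). The list also did not pass without any 1 of Hif1a+/- tumours 1, 2, 4 and 5, Hif1aKI/+ tumours 3 and 5 and Hif1a+/+ tumours 2, 3 and 5 (-1.06 to -0.79, camera adjusted p = 0.057 to 0.18).

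**Figure D3:**
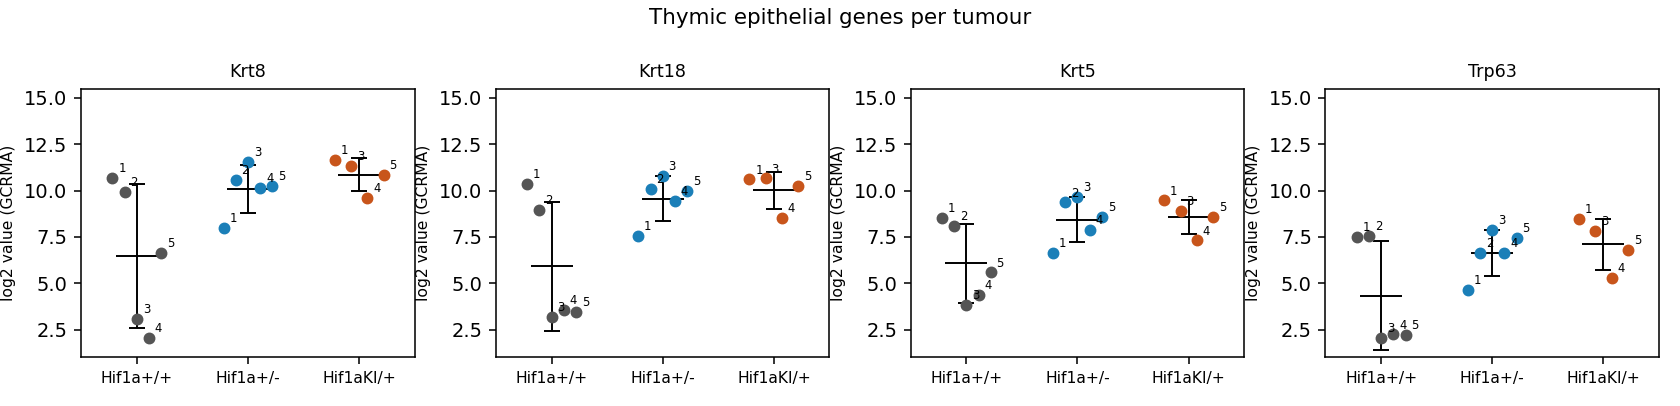
Log2 signal (GCRMA) of Krt8, Krt18, Krt5 and Trp63 in each tumour by genotype, with numbers giving the replicate and bars the mean and SD. Krt8 lies between 7.995 and 11.65 in Hif1a+/- and Hif1aKI/+ tumours and between 2.04 and 10.68 in Hif1a+/+ tumours.

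The Notch list did not pass in Hif1aKI/+ tumours (camera adjusted p = 0.13, 19 of 26 lower). Notch1 and Notch3 both differed by -0.07, Ptcra by -0.00015, Dtx1 by -1.24, Nrarp by -1.69, Hes1 by -2.10, Notch2 by -0.32, Igf1r by -1.41 (both group means below the low-mode boundary) and Il2ra by -5.32. The Hif1aKI/+ mean of Il2ra (2.41) lay below that boundary. The Notch ligand gene Jag2 was higher at 2.25 (SE 0.46) in all 4 tumours, and adjusted over the list alone it was the 1 Notch gene to pass (adjusted p = 0.0095), against 0 over all genes. Its Hif1a+/+ mean (3.27) lay below the low-mode boundary, so the size of its difference is uncertain. The immediate early gene Fos, at -1.63, likewise passed adjusted over its list alone (adjusted p = 0.0489) and not over all genes. The hypoxia-induced and HIF target genes did not shift (camera adjusted p = 0.87), with Zfp395 at 0.89, Vegfa at 0.76, Kdm3a at 0.38, Bnip3 at 0.30, Slc2a1 at 0.10, Pgk1 at -0.10, Ldha at -0.02 and Pfkfb3 at -0.55. Myc differed by 0.32.

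Other genes of small unadjusted p that did not pass were the Golgi transport gene Rab6b (4.89), Syt13 (2.10), Zfp707 (1.79), Tmem38a (1.51), Pglyrp2 (1.36), Plekhb2 (1.29), Mfap2 (1.17) and Mapk7 (1.16) on the higher side. On the lower side were Rpl39l (-6.42), Hopx (-2.60), Slc22a21 (-2.23), Frmd4b (-1.55), Svep1 (-1.41) and Pias2 (-1.02), all with an adjusted p of 0.984. Svep1, Tmem38a and Mfap2 had both group means below the low-mode boundary. Zfp707 had a Hif1a+/+ mean below it, and Hopx, Rpl39l and Slc22a21 a Hif1aKI/+ mean below it. Rab6b was raised in 3 of the 4 tumours, at 7.24, 6.95 and 11.58, and lay at background in the other tumours of all genotypes. Without Hif1a+/+ tumours 3, 4 and 5 the count of genes was 32, without Hif1aKI/+ tumour 5 it was 2 and without Hif1aKI/+ tumour 3 it was 1. In all 4 of 37 lists passed, 0 with an estimated correlation and 0 in fry, and 7 passed without Hif1aKI/+ tumour 1. With the epithelial covariate 5 passed at the preset correlation, among them fibroblast (statistic -1.39, camera adjusted p = 2.0e-05), macrophage (-1.09, 0.00052), Myc and ribosome biogenesis (-0.78, 0.011) and double-negative thymocyte genes (-0.92, 0.028).

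The direct comparison of Hif1a+/- with Hif1aKI/+ tumours asks whether the altered genotypes differ from each other. Growth and matrix genes were lower in Hif1a+/- tumours as groups by camera, but not with an estimated correlation (adjusted p = 0.83 to 0.85). The cell cycle list fell with 29 of 39 lower, with Mcm4 at -0.98, Cdc45 at -0.68, Mcm2 at -0.51 and Cdt1 at -0.37 (camera adjusted p = 0.0040, adjusted p = 0.85 with an estimated correlation). DNA repair genes had 20 of 22 lower, with Prkdc at -0.92, Chek1 at -0.70, Xrcc1 at -0.55 and Lig1 at -0.45 (camera adjusted p = 0.0052, adjusted p = 0.83 with an estimated correlation). Glycolysis genes had 17 of 18 lower, with Aldoc at -1.57 (both group means below the low-mode boundary), Slc2a3 at -0.54, Aldoa at -0.35 and Pkm at -0.30 (camera adjusted p = 0.0052, adjusted p = 0.83 with an estimated correlation). Myc and ribosome biogenesis genes had 22 of 27 lower, with Polr1a at -0.67, Polr1b at -0.66, Tfrc at -0.52 and Wdr43 at -0.42 (camera adjusted p = 0.0057, adjusted p = 0.85 with an estimated correlation).

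Fibroblast and matrix genes had 18 of 21 lower, with Fn1 at -1.0, Col6a1 at -0.89, Col6a2 at -0.83 and Thy1 at -0.14 (camera adjusted p = 0.0052, adjusted p = 0.85 with an estimated correlation). Macrophage markers had 18 of 22 lower, with Csf1r and Mpeg1 at -0.45 each, C1qb at -0.21 and Ctsb at -0.13 (camera adjusted p = 0.034, adjusted p = 0.85 with an estimated correlation). Wnt signalling genes had 9 of 13 lower, with Ccnd1 at -2.58, Lef1 at -1.56, Wnt5b at -1.44 and Fzd7 at -1.07 (camera adjusted p = 0.017, adjusted p = 0.68 with an estimated correlation, unadjusted p = 0.018). The Notch list was not past the threshold (camera adjusted p = 0.056), and Notch3 (-1.96) was lower in every Hif1a+/- tumour than in any Hif1aKI/+ tumour and Ptcra differed by -1.98, Jag2 by -1.0 and Adam10 by -0.31. The list did pass among genes above the median level (statistic from -0.55 to -1.21, camera adjusted p = 0.0047), without Hif1a+/- tumour 3 (-0.77, 0.0060) and in 5 other alternatives (0.023 to 0.049), though not with an estimated correlation (adjusted p = 0.83). The hypoxia-induced and HIF target genes did not shift (camera adjusted p = 0.44), with Car12 at -1.38, Zfp395 at -0.99, Pfkfb3 at 0.51, Jmjd6 at 0.39, Vegfa at -0.35 and Bnip3 at -0.33. Myc differed by -0.67, Slc2a1 by -0.21, Ldha by -0.14 and Pgk1 by -0.03.

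No single gene passed between Hif1a+/- and Hif1aKI/+ tumours (0 by limma, smallest adjusted p = 1.0, with 145 higher and 169 lower at an unadjusted p under 0.05), and 0 passed adjusted over a list alone. Smallest in p were the higher genes Bik (3.64), Sgip1 (2.68), 3830406C13Rik (2.15), Ccdc186 (1.88), Ifngr1 (1.67), Pcgf1 (1.49), Hint2 (1.44), C2cd2 (1.33), Fam149b (1.24) and Gtf3c6 (1.13). The lower genes were Rab6b (-4.89), Card10 (-4.17), Padi3 (-2.29), Ina (-2.05), Glis2 (-2.01), Tmc4 (-1.59), Syngr1 (-1.59), Polr3gl (-1.42), Tmem38a (-1.17) and Mfap2 (-1.06), the last 2 with both group means below the low-mode boundary. The Hif1a+/- means of Rab6b and Padi3 and the Hif1aKI/+ means of Ccdc186 and Pcgf1 also lay below it. Of the 7 list calls 0 passed without Hif1a+/- tumour 5, 3 without Hif1a+/- tumour 4 and 2 without Hif1aKI/+ tumour 3. Without Hif1a+/- tumour 5 the mean moderated statistic against other genes went from -0.71 to -0.17 for the cell cycle, from -0.69 to -0.06 for Myc and ribosome biogenesis and from -0.79 to -0.45 for DNA repair. It went from -0.83 to -0.525 for glycolysis (camera adjusted p = 0.13), from -0.86 to -0.62 for Wnt (0.13), from -0.60 to -0.31 for macrophage (0.44) and from -0.80 to -0.73 for fibroblast genes (0.062). Single calls also ended without Hif1a+/- tumour 1 (macrophage -0.45, camera adjusted p = 0.13) and without Hif1aKI/+ tumour 1 (macrophage -0.46 and fibroblast -0.49, 0.16), 4 (Wnt -0.63, 0.067) or 5 (cell cycle -0.46, 0.060, and DNA repair -0.59, 0.052). A single gene passed without Hif1aKI/+ tumour 3 and without Hif1a+/+ tumour 5.

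**Figure D4:**
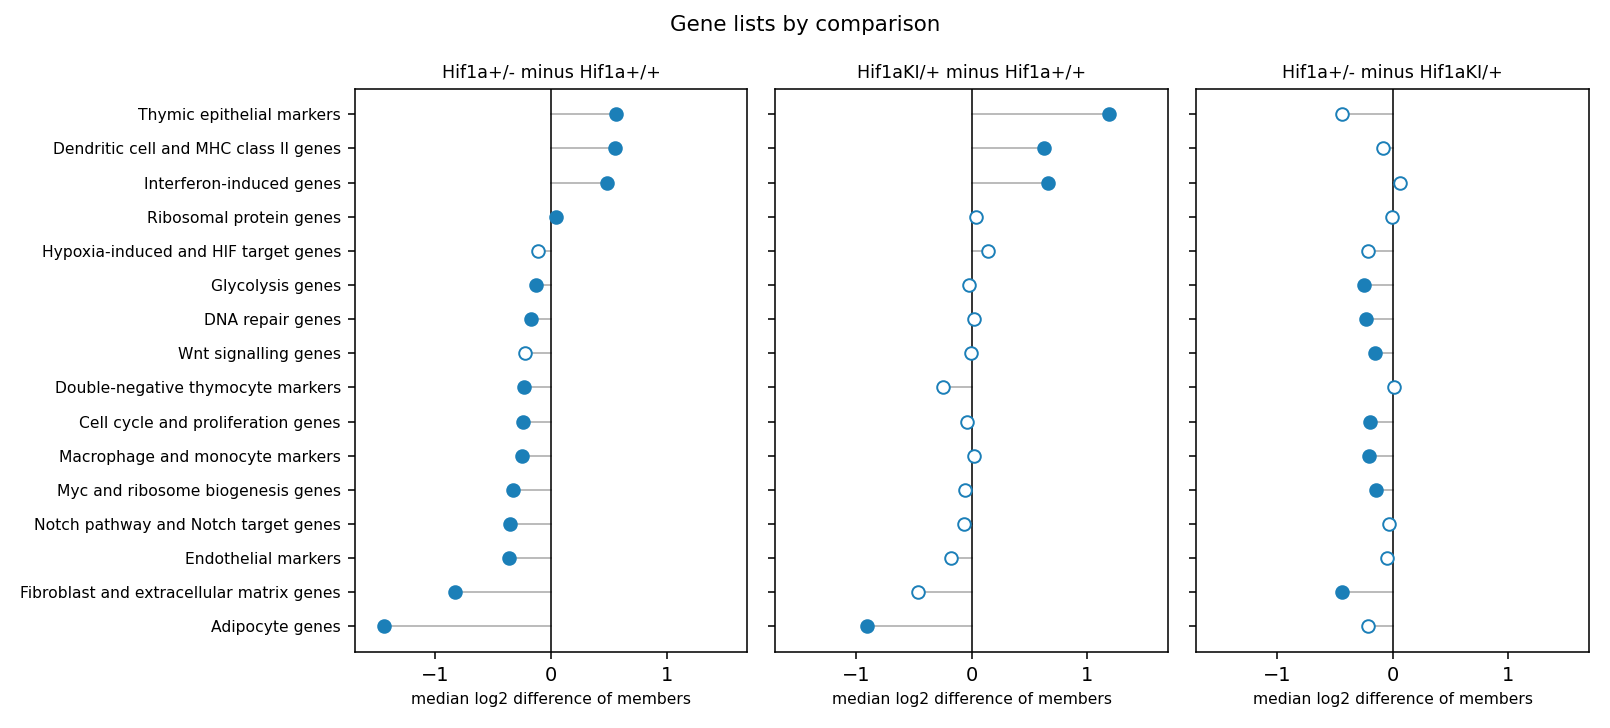
Median log2 difference of the measured members of each list past the threshold in at least 1 comparison, and of the hypoxia list, in the 3 comparisons. Filled points passed in camera at a preset correlation and open points did not, and 0 points pass with an estimated correlation.

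Among the remaining lists, T cell receptor signalling genes (14 of 21 higher in Hif1a+/- and 13 in Hif1aKI/+ than in Hif1a+/+, camera adjusted p = 0.16 and 0.58) and double-positive thymocyte markers (12 of 14 higher in both, adjusted p = 0.056 and 0.057) did not pass. Nor did the p53 target genes (adjusted p = 0.22 and 0.51), apoptosis regulators (0.086 and 0.66), mature T cell markers (0.89 and 0.58), T cell leukaemia oncogenes and suppressors (0.67 and 0.51), angiogenesis factors (0.73 and 0.87), HIF pathway components (0.98 and 0.58) and HIF-2 preferred targets (0.47 and 0.66). The same held for oxidative phosphorylation, unfolded protein response, TNF and NF-kB response, cholesterol synthesis, immediate early and heat shock, B cell, neutrophil, NK cell, erythroid, muscle and lung epithelial genes. Over all lists that did not pass, adjusted p ran from 0.056 to 0.98 in Hif1a+/- against Hif1a+/+, from 0.057 to 0.89 in Hif1aKI/+ against Hif1a+/+ and from 0.056 to 0.98 between the altered genotypes. The median, mean and test differed in sign in 5, 11 and 9 lists of these comparisons, 0 of which passed.

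The moderated F test for any difference among the 3 genotypes called 0 genes in limma, with 557 at an unadjusted p under 0.05 and a smallest adjusted p of 0.151, and 1 without Hif1a+/- tumour 1 or without Hif1aKI/+ tumour 3. Across genes, which are not independent replicates, the differences of Hif1a+/- and of Hif1aKI/+ from the shared Hif1a+/+ tumours had a Pearson r of 0.663, where simulated unchanged groups with the same shared controls gave 0.475. With the controls split between the comparisons r averaged 0.189, from 0.0666 to 0.318 over 20 splits. At an unadjusted p under 0.05, 116 genes were higher and 80 lower in both, where the simulated groups gave 56.6 and 56.9. In the simulations the genes varied independently, while in the tumours genes shift together. The simulations therefore do not give the spread of r or of the overlaps without an effect, and the excess over them does not test a shared one.

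Of the 50 measured genes nearest to Hif1a 0 passed in either comparison by limma. Over all genes only 2 passed in Hif1a+/- against Hif1a+/+ and 0 in Hif1aKI/+ against Hif1a+/+. A count of 0 here was therefore near certain or fixed in advance and tests nothing. Fisher's test treats the genes as independent. At an unadjusted p under 0.05 there were 6 in Hif1a+/- against Hif1a+/+, 12% against 7.92% of other genes (Fisher's exact p = 0.287), and 0 in Hif1aKI/+ against Hif1a+/+, against 4.37% of other genes (Fisher's exact p = 0.279). With 50 genes on each side it was 8 in the first (Fisher's exact p = 1) and 0 in the second, against 4.39% of other genes (Fisher's exact p = 0.0229), fewer than elsewhere.

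**Figure D5:**
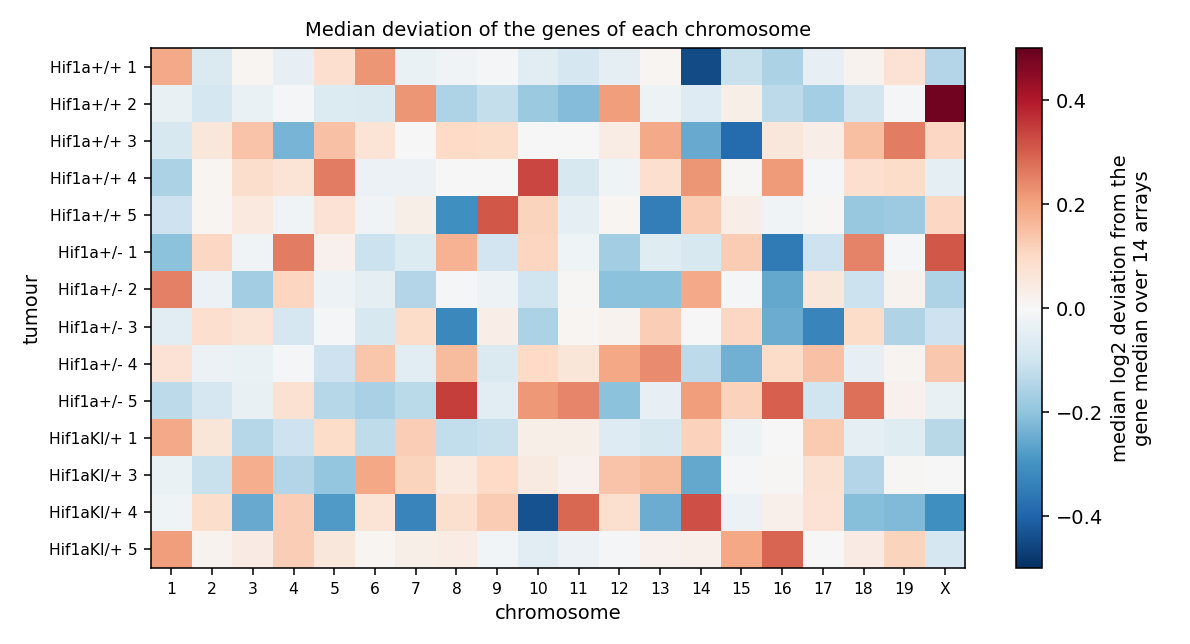
Median log2 deviation of the well expressed genes of each chromosome in each tumour from the gene's median over 14 arrays, in colour, with tumours in lines and chromosomes in columns. The medians run from -0.45 for chromosome 14 in Hif1a+/+ tumour 1 to 0.48 for chromosome X in Hif1a+/+ tumour 2.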

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

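The tests of T cell content, of epithelial tissue and of single tumours given here were chosen only after the results they concern were seen, and the splits of the arrays and the chromosome test were chosen before.

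A sample was singled out where its distance from the nearest other tumour of its genotype was large against the range of the group (Dixon's test). This met 44 of 558 group values, where a nominal 1 in 20 would be 27.9. That share holds for independent, normally distributed values. Many values here lie near background and list means share genes with single genes tested, so 44 against 27.9 does not test an excess. Of the 44, Hif1a+/- tumour 5 held 7, Hif1aKI/+ tumour 4 held 6 and Hif1a+/+ tumour 2 held 5.

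Among the list means, 7 of 111 were met. Hif1a+/- tumour 5 was lowest in its genotype for Myc and ribosome biogenesis genes (10.8, nearest tumour 11.57), DNA repair genes (9.51, nearest 10.1) and ribosomal protein genes (12.99, nearest 13.19), and highest for p53 target genes (8.37, nearest 7.93). Hif1a+/+ tumour 2 had the highest mean of hypoxia-induced and HIF target genes (9.5, nearest 8.92). Lung epithelial genes averaged 4.78 in Hif1a+/+ tumour 5 (nearest 2.7), and B cell markers averaged 6.95 in Hif1a+/- tumour 2 (nearest 5.62).

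In Hif1a+/+ tumours, the hypoxia-related genes Slc2a1 (13.01) and Pgk1 (14.23), the macrophage receptor gene Csf1r (13.89) and Card10 (3.63) stood apart in tumour 2, the last of these as the lowest. Notch1 was highest in tumour 3 (14.54), Epas1 in tumour 1 (2.04, at background), and Ldha (13.81) and Lig1 (10.11) were lowest in tumour 5.

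In Hif1a+/- tumours, Icam2 was lowest (9.94) and Il2ra highest (6.29) in tumour 1. Mfap2 (2.56), Rab6b (2.08) and Rpl39l (2.32) were highest in tumour 2, and Retn (2.19) and Tmem38a (3.46) in tumour 3. In tumour 4, Igf1r (2.19), P3h4 (8.14) and Slc22a21 (2.09) were lowest and Epas1 (2.03) was highest. In tumour 5, Car12 (3.24) and Irf7 (2.34) were lowest, and a Hif1a probe set near background was highest (3.15).

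In Hif1aKI/+ tumours, Mxi1 (11.73), Svep1 (2.93) and a Hif1a probe set near background (2.11) were highest and Rpl39l (2.1) was lowest in tumour 1, and Tmem38a (2.55) was lowest in tumour 3. In tumour 4, Adipoq (2.47), Mapk7 (8.95) and Retn (4.43) were highest and Brca2 (10.25), Hopx (1.85) and Mrc1 (7.48) were lowest. In tumour 5, Epas1 (2.82) and Il2ra (3.22) were highest and Oasl2 (6.7) and Rpl19 (14.42) were lowest. Many of these values lie below the low-mode boundary of 4.41, where a small absolute gap is enough.

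The lower Notch list in Hif1a+/- tumours was weighed first, and it was picked from 37 lists after their results were seen. Of 100 splits of the arrays of both groups, 2 shifted the list as far, the real one included (mean moderated statistic against other genes -1.10, highest other -1.14), which argues against chance for this list taken alone but does not allow for the choice among lists. A lower share of T cells would lower T cell receptor genes with it. Their median difference was 0.117 (95% bootstrap interval over genes -0.0116 to 0.402), against -0.358 for the Notch list. The interval does not measure the spread between tumours. By tumour, the mean of the T cell receptor list ran from 9.844 to 10.603 in Hif1a+/- and from 9.66 to 10.346 in Hif1a+/+. These values go against a lower share as the whole cause but do not exclude it as a part. No single tumour carried the call at the preset correlation, since the highest camera adjusted p over the fits without 1 array was 0.00388. These fits do not test 2 tumours together. The mean of the Notch list was 6.002 and 6.202 in Hif1a+/- tumours 2 and 5, against 6.823, 7.254 and 7.181 in tumours 1, 3 and 4. In Hif1a+/+ tumours it ran from 7.191 to 7.904. A biological difference with 1 Hif1a allele stays possible, but Notch activity was not measured. The list mean of the Hif1aKI/+ tumours, from 6.884 to 7.19, also lay below the lowest Hif1a+/+ tumour at 7.191. A mixture of lymphomas of different stages was not tested and stays open. The list call itself does not hold with an estimated correlation.

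The higher thymic epithelial list in Hif1aKI/+ tumours was weighed next, and it too was picked from 37 lists after their results were seen. Of 100 splits, 9 shifted the list as far (real value 1.72, highest other -2.89), so chance cannot be excluded. The highest camera adjusted p without 1 array was 0.000992, but these fits do not test several tumours together. The list mean was 3.75, 3.888 and 4.053 in Hif1a+/+ tumours 3, 4 and 5, against 7.054 and 5.804 in tumours 1 and 2. In Hif1aKI/+ tumours it ran from 5.939 to 7.328, so the difference rests mainly on Hif1a+/+ tumours 3, 4 and 5. More epithelial tissue in the pieces sampled is a candidate explanation. Of 40 general epithelial genes written down, the 21 measured outside the list and above the low-mode boundary in at least 1 tumour were compared. Their median difference was 0.952 (95% bootstrap interval over genes 0.0705 to 1.31), with 15 of them higher. Lamb3, Dsc2 and Dsg2 led, while Tfap2c and Grhl2 were lower. That interval treats the genes as independent and does not measure the spread between tumours. An earlier test planned for this point, which did not decide it, was set aside because it compared tumours grouped by their own epithelial signal, so this result is weaker than a planned one. The thymus itself expresses these genes, so residual thymus and a change within the tumours stay open.

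Genes of one chromosome shifted together in single tumours. Over 14 tumours and 20 chromosomes, 51 of 280 medians lay at least 0.2 from the gene medians and passed against random gene sets. Passing was an adjusted p under 0.05 by the Benjamini-Hochberg method against 1000 random gene sets of like size and mean level. Of the 51 medians 25 were higher and 26 lower, with 10 in Hif1aKI/+ tumour 4 and 0 in Hif1aKI/+ tumour 1. Gains or losses of whole chromosomes in the tumours may cause this, since the proximal and distal genes of a chromosome, in equal numbers, shifted together with a correlation of 0.755, against at most 0.176 in 200 re-pairings between different chromosomes. The shifts reached 0.48 for chromosome X in Hif1a+/+ tumour 2, -0.45 for chromosome 14 in Hif1a+/+ tumour 1 and -0.44 for chromosome 10 in Hif1aKI/+ tumour 4. In every cell, 3 copies in place of 2 would give 0.585 and 1 copy in place of 2 would give -1. These values are for chromosomes present in 2 copies, which need not hold for X in Hif1a+/+ tumour 2, where Xist was low. The number of shifted chromosomes per tumour did not differ between genotypes (exact permutation p = 0.571, 1 and 0.698), and DNA was not analysed here.

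For the counts of genes, 6 of 100 splits of the arrays gave as many as the 2 genes of Hif1a+/- against Hif1a+/+ (highest other 11), so chance cannot be excluded. For the 0 genes of Hif1aKI/+ against Hif1a+/+ (highest other 2), of Hif1a+/- against Hif1aKI/+ (19) and of the F test (29, over regroupings of all arrays) all 100 splits give at least as many by necessity, which tests nothing. Splits that call 19 or 29 genes may point to a structure of the samples other than genotype, which was not tested, while the median split called 0 genes for each pair of genotypes. For the counts of lists, 2 of 100 splits gave as many as the 14 of Hif1a+/- against Hif1a+/+ (highest other 14), which argues against chance for the full set of tumours. That count was 8 without Hif1a+/- tumour 5, against a median of 6 over the splits of all 10 tumours, so how far it depends on this tumour stays open. As for the other counts, 72 of 100 gave the 4 of Hif1aKI/+ against Hif1a+/+ (highest other 12) and 42 of 100 the 7 of Hif1a+/- against Hif1aKI/+ (highest other 11), where chance cannot be excluded.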

How the results depend on the processing

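The fits without Hif1a+/+ tumours 3, 4 and 5, with the thymic epithelial covariate and with the cell cycle covariate were chosen only after the results were seen. The first leaves out tumours of low keratin signal, so the fall of the epithelial list in it is built in and tests nothing. The cause was not tested for any change given here, apart from fewer arrays or fewer genes where these are named. The 2 genes of Hif1a+/- against Hif1a+/+ became 0 with the filter on level, quantile normalization, median centring, a fit of only 2 groups, the replicate block, all probe sets, and the Y-linked, epithelial and cell cycle covariates, 1 with trend and robust moderation and with a log2 minimum of 1, and 3 at an adjusted p of 0.10. Array weights gave 2, as did the mean of probe sets, where Dhx15 did not pass (limma adjusted p = 0.424) and Frmd4b did (0.0494). Without Hif1a+/+ tumours 3, 4 and 5 it was 45, with 32 for Hif1aKI/+ against Hif1a+/+ and 28 in the F test. The 14 lists of Hif1a+/- against Hif1a+/+ became 9 with the filter (fewer genes), 0 with estimated correlation, 2 in fry and 8 without Hif1a+/+ tumours 3, 4 and 5. With the cell cycle covariate the count was 9, and the lists lost included Myc and ribosome biogenesis, DNA repair, glycolysis and double-negative ones. It was 11 with median centring (losing glycolysis, DNA repair, double-negative and ribosomal lists), 11 with array weights (losing glycolysis, double-negative and macrophage lists), 12 with the Y-linked covariate (losing DNA repair and endothelial lists) and 12 with the epithelial covariate (losing DNA repair, MHC class II, endothelial and ribosomal lists). The ribosomal list was also lost with the filter (0.55, camera adjusted p = 0.10) and the mean of probe sets (0.54, 0.14), and the macrophage list with the filter (-0.74, 0.069). Those of Hif1aKI/+ against Hif1a+/+ became 0 with estimated correlation, 0 in fry and 5 with the epithelial covariate, which loses MHC class II, interferon and adipocyte lists. Without Hif1a+/+ tumours 3, 4 and 5 it was 4, with MHC class II (0.01), interferon (0.35) and adipocyte genes (-0.86) lost and fibroblast (-1.54), macrophage (-1.07) and double-negative genes (-1.05) gained. The adipocyte list was also lost with median centring, array weights, 2 groups, the block and the cell cycle covariate (-1.13 to -0.95, camera adjusted p = 0.051 to 0.11). Those of Hif1a+/- against Hif1aKI/+ became 0 with estimated correlation, 0 in fry, 3 with the epithelial covariate and 1 with the cell cycle covariate. The epithelial covariate lost glycolysis, Myc and ribosome biogenesis, macrophage (-0.35) and fibroblast (-0.48) lists. The cell cycle covariate lost glycolysis, Myc and ribosome biogenesis, DNA repair (-0.35), macrophage and Wnt lists. Median centring lost the macrophage list (camera adjusted p = 0.066) and the filter lost the Wnt list (0.061).

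The correlation of fold changes was 0.609 with the filter, 0.189 with split controls, 0.792 without Hif1a+/+ tumours 3, 4 and 5 and 0.738 with the epithelial covariate. The lower Hif1a signal of Hif1aKI/+ was -0.80 (exact permutation p = 0.0667) without those tumours, where fewer arrays limit p. Directions turned for MHC class II genes (-0.0756) and thymic epithelial genes (-0.360) of Hif1a+/- against Hif1a+/+ without those tumours, and for Myc and ribosome biogenesis genes (0.0584) of Hif1a+/- against Hif1aKI/+ with the cell cycle covariate (list values are mean moderated statistics against other genes). Of 6542 values compared, 91 uncalled ones differed in sign.

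Leaving out 1 array at a time, the gene counts ran from 0 to 1 (Hif1a+/- against Hif1a+/+, never Stab1 or Dhx15), 0 to 2 (Hif1aKI/+ against Hif1a+/+, 2 without Hif1aKI/+ tumour 5), 0 to 1 (Hif1a+/- against Hif1aKI/+) and 0 to 1 (F test), and the list counts from 8 (without Hif1a+/- tumour 5) to 17, 3 to 7 and 0 (without Hif1a+/- tumour 5) to 10. The correlation ran from 0.589 to 0.721, the Hif1a difference from -0.732 to -0.566 for Hif1aKI/+ and from -0.193 to -0.0347 for Hif1a+/-, and the Epas1 difference from 0.0264 (without Hif1aKI/+ tumour 5) to 0.294 (exact permutation p = 0.0357 without Hif1aKI/+ tumour 3). Genes flanking Hif1a gave 0 past the threshold by limma under the alternatives run, and with 50 on each side 8 and 0 at an unadjusted p under 0.05 (Fisher's exact p = 1 and 0.0229). A pseudocount did not apply, since the values are log2. Signal over background limits the 28.5% of genes below the low-mode boundary.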

Other observations

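The genes given here were chosen only after their values were seen.

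T cell lymphoma genes varied between tumours within each genotype. Cdkn2a, which encodes p16 and p19Arf, lay at 2.17 in Hif1a+/+ tumour 2 and between 7.45 and 10.66 in the other 13 tumours. Il2ra, a marker of early thymocytes, lay between 6.90 and 11.42 in Hif1a+/+ tumours 1 to 4 and at 2.14 in tumour 5, and among the other genotypes exceeded the low-mode boundary of 4.41 in Hif1a+/- tumour 1 alone (6.29). Dntt, the terminal transferase gene of immature lymphocytes, lay between 12.82 and 14.07 in 13 tumours and at 10.28 in Hif1a+/+ tumour 4. Cd8b1 was 11.68 ± 0.50 (SD, n = 5) in Hif1a+/-, 11.81 ± 0.31 (SD, n = 4) in Hif1aKI/+ and 10.82 ± 0.54 (SD, n = 5) in Hif1a+/+ tumours. Rpl39l, a paralog of a ribosomal protein gene, lay at background in Hif1a+/- and Hif1aKI/+ tumours and between 2.82 and 13.12 in Hif1a+/+ tumours.

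The labels give no sex. Xist, expressed from the inactive X chromosome of females, was 12.68 in Hif1a+/- tumour 1, 11.97 in Hif1aKI/+ tumour 1 and 12.57 and 11.64 in Hif1a+/+ tumours 3 and 5, and at most 3.85 in the others. The Y-linked gene Eif2s3y was between 2.09 and 2.29 in the same 4 tumours and between 7.46 and 12.42 in the other tumours, with 7.81 in Hif1a+/- tumour 3, 8.92 in Hif1a+/+ tumour 2 and 7.46 in Hif1a+/+ tumour 4 at the low end.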
